A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

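Small RNAs were measured by sequencing in 8 libraries of the budding yeast Saccharomyces cerevisiae. The libraries cover 2 genotypes and 2 stages, with 2 libraries in each of the 4 groups. Budding yeast lacks an RNA interference pathway of its own. The DCR1 AGO1 strain (DA) carries a reconstituted pathway in which Dicer, made from DCR1, cleaves paired RNA into small RNAs and Argonaute, made from AGO1, binds them; the wild type (WT) carries neither gene. Cells were grown in YPD, a rich glucose medium for vegetative growth, or sampled 8 h after induction of meiosis in sporulation medium (SPII8h). Per the labels, total RNA was extracted with hot phenol, libraries were made with a TruSeq small RNA kit, and reads were aligned with Bowtie2, whose version is not given in the sources used here.

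The deposited values are a signal per annotated feature: reads per base of the feature, multiplied by 1 factor per library. The file lists 12026 features with a class, chromosome, start, end and strand: 5798 genes, 1798 XUTs, 925 CUTs, 847 SUTs, 809 dubORFs, 746 mSUTs, 706 MUTs, 299 tRNAs, 77 snoRNAs, 15 ncRNAs and 6 snRNAs. XUTs are transcripts degraded by the cytoplasmic exonuclease Xrn1, CUTs are degraded by the nuclear exosome, SUTs are stable unannotated transcripts and MUTs are meiotic ones; the meaning of mSUT and dubORF is not given in the sources used here. Every value multiplied by the feature's length was a whole multiple of the library's factor, with a tolerance of 0.01, so whole reads were recovered from the values for 100% of features. Summed over features, the recovered reads came to 97405 and 277549 in the WT_YPD libraries, 427349 and 206085 in WT_SPII8h, 5852540 and 6374885 in DA_YPD, and 7408095 and 8136886 in DA_SPII8h. Reads shared by features that overlap on the same strand count more than once in these sums. The scaled totals lay between 92674.6 and 115786, so the factors bring the libraries close to the same total; what the authors computed them from is not given in the sources used here, nor are the selected read lengths and the treatment of reads that map to several places.

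Coordinates are those of the file. Of 5942 feature IDs that matched an R64 locus tag, 5910 (99.5%) had the same start and end. Repeats were counted as 22-mers of a feature that occur more than once in the genome, copies within the feature included. Of 559 features made wholly of such 22-mers, 378 (67.6%) were listed at 0 in all 8 libraries, against 269 (2.88%) of the 9348 features with none, so values of near-identical copies are uncertain. Another feature overlapped 2540 features (21.1%) on the same strand, and such features share reads. Of 2071 features covered over 90% by an opposite-strand feature, 138 had equal reads on both strands in a DA_YPD library. The opposite feature was counted over its whole length, so unequal reads alone do not show that reads were assigned by strand.

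Densities are given as scaled reads per kb, as mean and SD of 2 libraries. A count of 0 allows up to 3 reads over a group, which for a feature of 1 kb is 0.751 scaled reads per kb in WT_YPD, 0.500 in WT_SPII8h, 0.0255 in DA_YPD and 0.0220 in DA_SPII8h. Ratios against a group at 0 are lower bounds against that floor, and other ratios of reads have a 95% counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers as far as the labels say.

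Densities were analysed as deposited, as the log2 of the value plus a pseudocount of 0.0966 scaled reads per kb, the 10th percentile of all values above 0. Features above 0 in at least 2 of the 8 libraries were tested, 10714 in all. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with a trend and robust moderation of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 4 contrasts were DA against WT in YPD, DA against WT at SPII8h, and SPII8h against YPD in DA and in WT; the interaction tested whether the stage difference depended on genotype. The comparisons, tests, threshold, gene lists, the rule for named features and the alternative settings listed at the end were fixed before the data were examined. At that time the plan allowed for whole counts or another unit in the file. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

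The procedure was tested on simulated data in the form of DA_SPII8h against WT_SPII8h at the observed depths, with 10582 tested features. Of 10382 unchanged features limma called 283 higher and 6 lower. Of 25 features raised 16-fold limma recovered 18, of 25 raised 8-fold 15, of 25 raised 4-fold 9 and of 25 raised 2-fold 1. Of 25 lowered 16-fold it recovered 8, of 25 lowered 8-fold 10 and of 25 lowered 4-fold 3. False higher calls thus outnumbered the raised features recovered, so the adjusted threshold did not hold for higher calls in this simulation. With all libraries thinned, 3 of 7669 unchanged features were called higher and 3 lower. The alternative limma-voom on recovered reads called 8 unchanged features higher and 1361 lower.

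Shares are the scaled reads of a class over the library total, which is the sum over features with shared reads counted more than once. Shares and class medians were compared by an exact two-sided permutation test of 2 against 2 libraries. Pervasive noncoding stands for XUT, SUT, mSUT, CUT and MUT together, and structured for the annotated tRNA, snoRNA, snRNA and ncRNA. Features with at least 200 bases covered by a feature on the opposite strand were set against features with none, by a two-sided permutation test over features with 100000 permutations; features are not independent replicates. The 12 gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as the alternative, adjusted over the lists and the 4 contrasts; the interaction was adjusted over the 12 lists. They are early meiotic recombination and synapsis, middle meiotic divisions and prospore membrane, spore wall, cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, gluconeogenesis with glyoxylate cycle and respiration, mitotic G1 and S phase cyclins and mating, genes with a published antisense transcript, RNA decay and antisense surveillance, heat shock and environmental stress, and mitochondrially encoded genes. Of 19 genes in the published antisense list 18 were found, and 29 of 30 ribosomal protein genes were tested. With an estimated correlation camera also takes its p from the few residual degrees of freedom of 8 libraries in 4 groups. For ribosome biogenesis in YPD the estimate was −0.0336, under the preset, yet the camera adjusted p went from 9.61e-06 to 0.0712. A list that did not pass with an estimated correlation is therefore not shown to owe its preset result to correlated genes.

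Named features are, for each contrast, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold whose libraries do not overlap between groups, the 2 largest rises and falls of each noncoding class (dubORFs were not counted as a class here), and up to 4 members of each list with the smallest p. The interaction names 3 features in each direction. Features singled out otherwise are said to be chosen after their values were seen. A subset of the named features, taken in the same order, was followed through every alternative: all protein-coding genes, the leading feature of each direction per noncoding class, the leading 2 per list and the 6 of the interaction.

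The alternative settings fixed beforehand were the pseudocount divided or multiplied by 10, no filter, a filter on the mean, median centring, quantile scaling, no trend in the spread, the 4 libraries of a contrast alone, replicate number as a block, each library left out in turn, classes without the top 1% of features or with features above 0 in all libraries, and an opposite-strand overlap of any size or of at least 0.5 of the feature. Chosen after seeing the data were scaling to the snoRNA sum, limma-voom on recovered reads, thinning of all libraries to the shallowest, a separate spread per genotype, a set without repeated features and hosts of structured RNAs, class shares without genes that host structured RNAs, and gene lists against protein-coding genes alone. The labels give no batch. All 8 deposited columns were used.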

Results

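Small RNAs were counted over 12026 annotated features of the budding yeast genome in 8 libraries, 2 from each of 4 groups. Wild-type cells (WT) and cells with a reconstituted RNA interference pathway (DA, DCR1 AGO1) were each sampled during vegetative growth in YPD and 8 h after induction of meiosis (SPII8h). The WT libraries were shallow, with 97405 and 277549 reads summed over features in YPD and 427349 and 206085 at SPII8h. The same sums for the DA libraries were 5852540 and 6374885 in YPD and 7408095 and 8136886 at SPII8h. Reads shared by features that overlap on the same strand count more than once in these sums and in the shares below. Reads were seen at 41.1 to 57.9% of features in the WT libraries and at 83.0 to 86.2% in the DA libraries. The Pearson correlation of log2 densities across features between the 2 libraries of a group was 0.762 in WT_YPD, 0.806 in WT_SPII8h, 0.973 in DA_YPD and 0.980 in DA_SPII8h; features are not independent replicates. Densities are scaled reads per kb, as mean ± SD of 2 libraries, and log2 changes carry the standard error of limma's fit to all 8 libraries. The labels do not say whether the libraries of a group are separate cultures, so each p measures the spread between samples only, which may be technical. An exact test of 2 against 2 libraries cannot give a p below 0.33.

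The comparison of DA with WT in YPD asks which transcripts give rise to small RNAs when Dicer and Argonaute are present in vegetative cells. Pervasive noncoding transcripts held 56.1 ± 0.421% of the scaled reads in DA_YPD (SD, n = 2) and 2.86 ± 0.271% in WT_YPD, a 19.6-fold difference (exact permutation p = 0.33, the smallest it can give). XUTs, which the exonuclease Xrn1 degrades, held 29.5% against 0.936%, and mSUTs 17.6% against 0.971%. SUTs held 7.43% against 0.497% and the meiotic MUTs 0.912% against 0.0595%, while CUTs differed least, with 0.753% against 0.394%. The structured RNAs, with snoRNAs the main part, held 2.47 ± 0.579% in DA_YPD and 61.1 ± 3.99% in WT_YPD, and genes held 40.5 ± 0.187% and 35.5 ± 3.6%. A single locus weighs on these shares: XUT0792 and the mSUT SUT2486, which lies within it on the same strand and shares its reads, took 14.2% and 14.1% of DA_YPD reads, much of the shares of their classes. Without the top 1 percent of features the pervasive shares were 46.9% in DA_YPD and 5.61% in WT_YPD, a much smaller ratio, and the gene shares turned to 51.3% in DA_YPD and 88.5% in WT_YPD. The top 1 percent also held most structured RNA reads of WT_YPD, so the other WT_YPD shares grew as the total shrank, not through this locus alone. Reads of a snoRNA inside an intron also count for its host gene, and without such genes the gene shares were 40.4% in DA_YPD and 30.4% in WT_YPD.

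Single noncoding features rose from no reads in the WT_YPD libraries to high density in DA_YPD. SUT2382 (chromosome 14, 569940 to 570028) went from 0 to 548 ± 53.8, at least 64.8-fold, and SUT597 (chromosome 8, 507712 to 508688), opposite YHR204W and overlapped by XUT1319 on its own strand, from 0 to 31.9 ± 2.01, at least 41.6-fold. CUT884 (chromosome 16, 134894 to 135526), opposite the flavin carrier gene FLC1 (YPL221W), went from 0 to 44.4 ± 2.28, at least 37.5-fold (limma log2 change 8.85 ± 0.24, adjusted p = 9.39e-05). The meiotic transcript MUT1059 (chromosome 12, 687989 to 688525) had 4.04 ± 3.08 in WT_YPD and 780 ± 180 in DA_YPD, 153-fold (85.6 to 307), and shares reads with XUT1505. ICR1 and PWR1, noncoding RNAs on opposite strands upstream of the flocculin gene FLO11, rose 9.39-fold (5.69 to 16.8) and 3.37-fold (1.88 to 6.78). The snRNA LSR1, the U2 RNA of the spliceosome, rose 2.30-fold, from 115 ± 1.67 to 261 ± 14.8, a rise that median centring turned to −0.08 on the log2 scale. By class, 966 of 1579 tested XUTs were higher and 24 lower, with 440 and 24 of 799 SUTs, 287 and 6 of 483 mSUTs, 390 and 41 of 805 CUTs, 248 and 5 of 481 MUTs and 360 and 29 of 669 dubORFs. The WT_YPD libraries were at 0 in 886 of the 1579 XUTs, and with such features at their bound the median change of XUTs was 0.

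The 8 protein-coding genes with the largest rises have varied functions, and no list drawn from them was tested. The α-glucosidase gene IMA5 (YJL216C, chromosome 10, 24341 to 26086) had 0.668 ± 0.675 in WT_YPD and 146 ± 1.09 in DA_YPD, 340-fold (116 to 1648). Its neighbour HXT8 (YJL214W, chromosome 10, 26887 to 28596), of the hexose transporter family, rose from 1.27 ± 0.139 to 298 ± 13.9, 226-fold (119 to 493), and the alcohol acetyltransferase gene ATF1 (YOR377W, chromosome 15, 1046226 to 1047803) rose 107-fold (41.9 to 394). The galactokinase gene GAL1 (YBR020W, chromosome 2, 279021 to 280607) went from 0 to 17.4 ± 0.00232, at least 36.7-fold (limma log2 change 7.50 ± 1.01, adjusted p = 0.00215). TDA8 (YAL064C-A, chromosome 1, 13363 to 13743), of unknown function, rose at least 32.1-fold, and 20.6% of its 22-mers recur in the genome. The others of the 8 were OSI1 (128-fold against 1 WT_YPD read, 23.0 to 5069), UIP5 (68.1-fold, 29.2 to 210) and YOR376W-A (at least 3.65-fold). HMS2 (YJR147W, chromosome 10, 704196 to 705272), which encodes a protein resembling the heat shock factor and overlaps YJR146W on the same strand, rose from 4.03 ± 0.871 to 298 ± 13.3, 79.9-fold (49.2 to 140). The isocitrate lyase gene ICL1 (YER065C) of the glyoxylate cycle rose 39.1-fold (23.3 to 71.6). Genes of meiosis were among those that rose in these vegetative cells. The sporulation MAP kinase gene SMK1 (YPR054W) went from 0 to 13.5 ± 0.126, at least 20.9-fold, the prospore membrane SNARE gene SPO20 (YMR017W) at least 9.85-fold, and the helicase gene HFM1 (YGL251C) at least 12.9-fold.

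Several genes of branched-chain amino acid synthesis were among the 8 largest gene falls in DA_YPD; no list of such genes was tested. LEU1 (YGL009C, chromosome 7, 476313 to 478652), the isopropylmalate isomerase of leucine synthesis, fell from 61.8 ± 18.5 to 0.216 ± 0.0494, 319-fold lower (limma log2 change −7.61 ± 0.28, adjusted p = 0.000107). The transaminase gene BAT1 (YHR208W, chromosome 8, 517532 to 518713) was 141-fold lower, the acetolactate synthase gene ILV2 (YMR108W, chromosome 13, 484084 to 486147) from 53.7 ± 9.44 to 0.544 ± 0.0105 and the mitochondrial carrier gene OAC1 (YKL120W, chromosome 11, 217344 to 218318) 69.5-fold lower. Scaled to the snoRNA sum, these 4 genes stayed lower, with log2 changes of −3.17, −2.21, −1.72 and −1.09. YER053C-A, with a fall (−6.73) between those of BAT1 and ILV2, rested on 4 WT_YPD reads against 0. The histone H4 gene HHF2 and the ribosomal protein gene RPL41B also fell, but 55.0% and 84.2% of their 22-mers are repeated in the genome, so their values are uncertain. Of the snoRNAs, 75 of 77 were lower and 0 higher (median log2 change −4.81). The snoRNA snR62 fell from 267 ± 75.2 to 5.78 ± 0.122, 41.5-fold lower. SCR1, the RNA of the signal recognition particle, was 34.2-fold lower, and 114 of 204 tRNA genes were lower.

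Lists of genes of growth and translation were lower in DA_YPD. Of 29 ribosomal protein genes 25 were lower and 0 higher (26 and 0 adjusted over the list alone), while scaled to the snoRNA sum 0 were lower and 14 higher. Their median log2 change was −3.62 (limma camera, adjusted p = 4.34e-11, and adjusted p = 0.0837 with an estimated correlation). RPS3, of the small subunit, fell from 1018 ± 132 to 25.5 ± 2.21, 41.6-fold lower. Of 29 ribosome biogenesis genes 16 were lower and 1 higher (17 and 1 adjusted over the list alone), against 0 and 15 with snoRNA scaling. The biogenesis median was −1.83, and −3.26 with genes at 0 at their bound and no pseudocount (adjusted p = 9.61e-06, and adjusted p = 0.0712 with an estimated correlation), and the gene that rose was NSR1, of nucleolin, 6.78-fold (4.47 to 10.8). Of 17 glycolysis genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone), against 0 and 13 with snoRNA scaling. The glycolysis median was −2.55 (adjusted p = 8.53e-07, and adjusted p = 0.0837 with an estimated correlation), and the aldolase gene FBA1 was 30.4-fold lower. Of 25 genes of gluconeogenesis and respiration 13 were lower and 3 higher (13 and 3 adjusted over the list alone), against 0 and 17 with snoRNA scaling. Their median was −1.0 (adjusted p = 0.000229, and adjusted p = 0.196 with an estimated correlation).

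Of 20 heat shock genes 14 were lower and 3 higher (14 and 3 adjusted over the list alone), against 0 and 10 with snoRNA scaling. The heat shock median was −2.16 (adjusted p = 4.40e-05, and adjusted p = 0.190 with an estimated correlation), and the disaggregase gene HSP104 was 37.4-fold lower. Of 21 RNA decay genes 10 were lower and 2 higher (10 and 2 adjusted over the list alone), against 0 and 16 with snoRNA scaling. The RNA decay median was −0.98 (adjusted p = 0.00708, and adjusted p = 0.116 with an estimated correlation). The decapping enzyme gene DCP2 was 26.5-fold lower, with a log2 change of 0.24 under snoRNA scaling. Of the 8 mitochondrially encoded genes 7 were lower and 0 higher (7 and 0 adjusted over the list alone), against 0 and 3 with snoRNA scaling. The mitochondrial median was −3.71 (adjusted p = 0.000217, and adjusted p = 0.190 with an estimated correlation). Tested against protein-coding genes alone, the RNA decay list and the gluconeogenesis and respiration list no longer passed (adjusted p = 0.433 and 0.0570).

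Early meiotic genes had 10 higher and 2 lower of 30 in YPD (10 and 2 adjusted over the list alone). Their median was 0.65, and 0 with genes at 0 at their bound (adjusted p = 0.274). Against protein-coding genes alone the early, middle and published antisense lists passed as higher (adjusted p = 0.000774, 0.00972 and 0.0237), whereas with an estimated correlation against all features they did not (adjusted p = 0.547, 0.904 and 0.783). Middle meiotic genes had 7 higher and 3 lower of 30 (6 and 3 adjusted over the list alone, median 0.17, and 0 at the bound, adjusted p = 0.760). Spore wall genes had 4 and 2 of 17 (4 and 2 adjusted over the list alone, median 0.30, and 0 at the bound, adjusted p = 0.901). Mitotic cyclin and mating genes had 4 and 2 of 14 (4 and 2 adjusted over the list alone, adjusted p = 0.957), with a median of 0.57 that was −0.66 with genes at 0 at their bound. Genes with a published antisense transcript had 9 higher and 5 lower of 18 (9 and 5 adjusted over the list alone, median 0.996, adjusted p = 0.760). These counts depended on the method, and in all but the published antisense list the balance turned with limma-voom. A gene with 0 WT_YPD reads cannot be seen to be lower in DA, and 19 early and 17 middle genes had none. In the simulation at SPII8h limma-voom also called 1361 unchanged features lower, so the turn in the early and middle lists decides nothing. Higher and lower genes were 19 and 0 (early), 15 and 0 (middle), 11 and 0 (spore wall), 11 and 0 (cyclin and mating) and 16 and 0 (published antisense) with snoRNA scaling. With limma-voom they were 7 and 18, 5 and 21, 4 and 9, 3 and 7, and 8 and 7, and at equal depth the early and middle lists had 2 and 1 each.

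Limma called 5854 of 10714 features in YPD, 3547 higher and 2307 lower in DA. The split depended on the scaling: 1064 higher and 2039 lower with median centring, 2758 and 2681 with quantile scaling, 8162 and 21 when scaled to the snoRNA sum, and 2068 and 5480 with limma-voom, and these moved the median change of all features from 0.60 to −0.68, −0.21, 3.34 and −1.51. That median was also −0.16 at equal depth, 0.33 without WT_YPD replicate 1, 1.05 without WT_YPD replicate 2, 0.24 with a filter on the mean, and 1.70 and 0.08 with a 10 times smaller and larger pseudocount. Of the 3547 higher features 2370 were at 0 in both WT_YPD libraries, 1955 lay above the floor there, and 1063 were also higher in limma-voom and with all libraries thinned to the shallowest. In the simulation at SPII8h limma called 283 unchanged features higher, so part of the higher calls may be false.

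**Figure D1:**
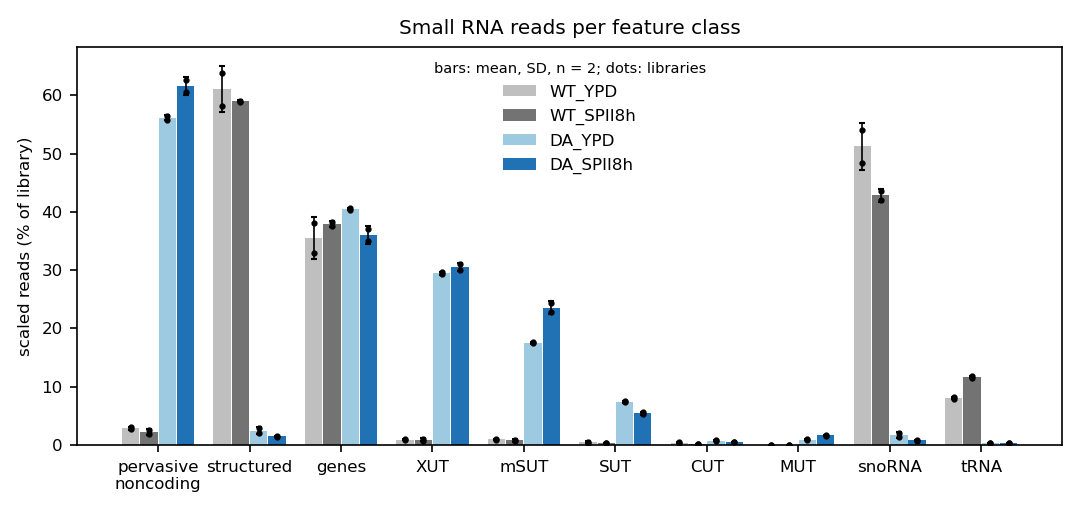
Share of scaled small RNA reads (percent of library) per feature class in the 4 groups; bars are means, error bars the SD of 2 libraries and dots the libraries. The pervasive noncoding share was 56.1% in DA_YPD and 61.6% in DA_SPII8h, against 2.86% in WT_YPD and 2.24% in WT_SPII8h.

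The same comparison at SPII8h asks which transcripts give rise to small RNAs during meiosis. Pervasive noncoding transcripts held 61.6 ± 1.48% of the scaled reads in DA_SPII8h and 2.24 ± 0.454% in WT_SPII8h (SD, n = 2), a 27.5-fold difference (exact permutation p = 0.33). XUTs held 30.5% against 0.914%, mSUTs 23.6% against 0.783%, SUTs 5.42% against 0.357%, MUTs 1.64% against 0.0818% and CUTs 0.456% against 0.102%. The structured RNAs held 1.47 ± 0.0604% against 59.0 ± 0.190%, and genes 36.0 ± 1.52% against 37.9 ± 0.452%. XUT0792 and the mSUT SUT2486, sharing reads, took 20.5% and 20.1% of the DA_SPII8h reads, and without the top 1 percent of features the pervasive shares were 47.9% and 4.64% and the gene shares 49.8% and 90.1%. Here too the top 1 percent held most structured RNA reads of the WT libraries, so the other WT shares grew as the total shrank. Without the genes that host structured RNAs the gene shares were 35.9% in DA_SPII8h and 26.9% in WT_SPII8h. SUT1213 (chromosome 4, 41913 to 42409), opposite YDL231C, went from 0 to 35.1 ± 1.01, at least 34.8-fold. CUT281 (chromosome 13, 23944 to 26104), opposite the phosphate transporter gene PHO84 (YML123C) and overlapped by XUT0683, was 218-fold higher (60.5 to 1805), and MUT681 (chromosome 8, 175414 to 176022), opposite YHR033W, was 253-fold higher against 1 WT_SPII8h read (45.4 to 9994). By class 819 of 1579 XUTs were higher and 29 lower, with 389 and 29 of 799 SUTs, 265 and 11 of 483 mSUTs, 299 and 18 of 805 CUTs, 225 and 16 of 481 MUTs and 288 and 32 of 669 dubORFs. The WT_SPII8h libraries were at 0 in 800 XUTs, and the median change of XUTs was again 0 with such features at their bound.

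The largest gene rises at SPII8h included FUS3 (YBL016W, chromosome 2, 192451 to 193512), the MAP kinase of the mating pathway, which went from 0 to 9.51 ± 0.107, at least 20.2-fold (limma log2 change 6.64 ± 0.28, adjusted p = 0.000133). AMF1 (YOR378W, chromosome 15, 1049511 to 1051058), which encodes an ammonium transporter, rose from 1.21 ± 0.112 to 125 ± 2.79, 106-fold (59.2 to 212). DCG1 (YIR030C, chromosome 9, 412036 to 412770), in the allantoin gene cluster, rose at least 15.2-fold, and HMS2 rose 48.9-fold (36.0 to 68.2). The G1 cyclin gene CLN2 (YPL256C) rose 15.3-fold against 2 WT_SPII8h reads (4.22 to 127), and IME4 (YGL192W), of the RNA methyltransferase needed for meiosis, rose from 1.66 ± 0.00305 to 6.13 ± 0.189, 3.67-fold (2.32 to 6.22).

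The largest gene falls at SPII8h were RPL7A, RPL7B and ASC1, each 185-fold, 154-fold and 147-fold lower, but these host the snoRNAs snR39, snR59 and snR24: in WT_SPII8h 5401 reads fell on snR39 and 5422 on RPL7A. They were followed by genes of spore formation. SPO19 (YPL130W, chromosome 16, 304387 to 305058), of the prospore membrane, fell from 37.8 ± 4.02 to 0.271 ± 0.0541, 142-fold lower (limma log2 change −6.69 ± 0.30, adjusted p = 0.000133). SPS2 (YDR522C, chromosome 4, 1483795 to 1485303), of the spore wall, was 120-fold lower, the chitin deacetylase gene CDA1 (YLR307W, chromosome 12, 745620 to 746525) 157-fold lower and SPS4 (YOR313C, chromosome 15, 901858 to 902874) 93.8-fold lower. With snoRNA scaling SPO19 and CDA1 stayed lower past the threshold, at −1.33 and −1.49, while SPS2 and SPS4, at −1.10 and −0.82, were no longer past it.

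**Figure D2:**
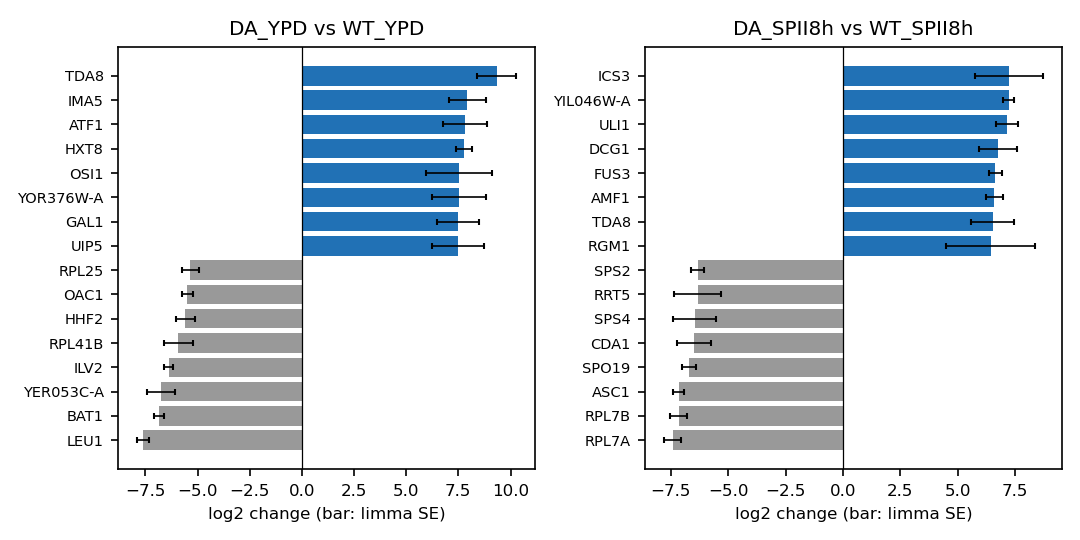
Limma log2 changes of the 8 protein-coding genes with the largest rises and the 8 with the largest falls with DCR1 AGO1, in YPD (left) and at SPII8h (right); error bars are standard errors of the fit to 8 libraries. TDA8 at 9.34 and LEU1 at −7.61 are the extremes in YPD, and ICS3 at 7.23 and RPL7A at −7.42 at SPII8h.

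Meiotic genes as groups were lower in DA_SPII8h. Of 30 middle meiotic genes 28 were lower and 0 higher (29 and 0 adjusted over the list alone), while scaled to the snoRNA sum 2 were lower and 5 higher. Their median log2 change was −5.17 (limma camera, adjusted p = 7.49e-13, and adjusted p = 0.0843 with an estimated correlation). Of 30 early meiotic genes 18 were lower and 4 higher (18 and 4 adjusted over the list alone), against 0 and 22 with snoRNA scaling. The early meiotic median was −2.64 (adjusted p = 0.000229, and adjusted p = 0.152 with an estimated correlation). The initiator gene IME1 was 49.7-fold lower, the recombinase gene DMC1 35.9-fold and the kinase gene IME2 38.0-fold, and their log2 changes were 0.08, 0.53 and 0.55 with snoRNA scaling. Of 17 spore wall genes 12 were lower and 0 higher (12 and 0 adjusted over the list alone), against 1 and 9 with snoRNA scaling. The spore wall median was −3.72 (adjusted p = 1.19e-05, and adjusted p = 0.215 with an estimated correlation). Of 25 gluconeogenesis and respiration genes 19 were lower and 2 higher (19 and 2 adjusted over the list alone), against 0 and 17 with snoRNA scaling. Their median was −3.62 (adjusted p = 7.90e-07, and adjusted p = 0.145 with an estimated correlation), and the citrate synthase gene CIT1 was 76.5-fold lower.

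Of 29 ribosomal protein genes 24 were lower and 0 higher at SPII8h (24 and 0 adjusted over the list alone), against 0 and 17 with snoRNA scaling. The ribosomal protein median was −2.52 (adjusted p = 5.96e-08, and adjusted p = 0.0837 with an estimated correlation). Ribosome biogenesis genes had 14 lower and 1 higher of 29 (14 and 1 adjusted over the list alone), against 0 and 16 with snoRNA scaling. The biogenesis median was −1.59, and −3.13 at the bound (adjusted p = 0.00429, and adjusted p = 0.101 with an estimated correlation). RNA decay genes had 12 lower and 1 higher of 21 (12 and 2 adjusted over the list alone), against 0 and 14 with snoRNA scaling. The RNA decay median was −2.27 (adjusted p = 0.000694, and adjusted p = 0.0837 with an estimated correlation). Heat shock genes had 13 lower and 3 higher of 20 (14 and 4 adjusted over the list alone), against 0 and 14 with snoRNA scaling. The heat shock median was −2.92 (adjusted p = 0.000282, and adjusted p = 0.224 with an estimated correlation). Of the 8 mitochondrial genes 6 were lower (6 adjusted over the list alone), against 0 in either direction with snoRNA scaling. The mitochondrial median was −5.15 (adjusted p = 0.000290, and adjusted p = 0.190 with an estimated correlation).

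Against protein-coding genes alone the early meiotic, ribosome biogenesis, RNA decay and heat shock lists no longer passed at SPII8h (adjusted p = 0.131, 0.654, 0.139 and 0.0557). The cyclin and mating list then passed as higher (adjusted p = 0.00524), but not against all features with an estimated correlation (adjusted p = 0.460). Glycolysis genes had 3 higher and 7 lower of 17 (3 and 7 adjusted over the list alone, median −0.62, adjusted p = 0.0768). Cyclin and mating genes had 4 and 1 of 14 (4 and 1 adjusted over the list alone, median 0.79, and 0.10 with genes at 0 at their bound, adjusted p = 0.397). Genes with a published antisense transcript had 6 higher and 6 lower of 18 (7 and 6 adjusted over the list alone, adjusted p = 0.901). The median of that list was 0.88, and 0.55 at the bound, and its mean 0.11, where the test pointed down. With snoRNA scaling these 3 lists had 16, 11 and 16 higher genes and 0 lower, and with limma-voom 1 higher and 8 lower, 3 and 5, and 9 and 8.

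At SPII8h limma called 5378 features, 2931 higher and 2447 lower in DA, and of the 2931 higher 1691 were at 0 in both WT_SPII8h libraries and 870 were also higher in limma-voom and at equal depth. Part of the higher calls may be false, since limma called 283 unchanged features higher in the simulation of this comparison. The split was 1584 and 791 with median centring, 8362 and 29 when scaled to the snoRNA sum and 2070 and 5584 with limma-voom, with a median change of all features of 0.31 moving to 0.59, 3.74 and −1.65, and −0.15 with quantile scaling. It was 0.17 without DA_SPII8h replicate 2, 0.47 without WT_SPII8h replicate 1, 0 at equal depth, 0.00482 with a filter on the mean, and 1.05 and 0.04 with a smaller and larger pseudocount.

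Overlap with a feature on the opposite strand was compared because paired RNA needs both strands. In YPD the median log2 change of 1973 genes with at least 200 bases of such overlap was 0.29 and that of 3126 genes with none was −1.31, a difference of 1.60 (1.66 to 1.81 over the 4 pairs of libraries; permutation p = 1e-05, the smallest the permutations can give). At SPII8h the medians were −0.36 and −1.60, a difference of 1.24 (1.23 to 1.34; permutation p = 1e-05). The pairs rest on single libraries and the difference on group means, so the range of the pairs need not hold the difference. The size of the difference depended on the settings: it was 0.69 and 0.41 with a 10 times larger pseudocount, 2.27 and 1.80 with a smaller one and 2.50 and 2.11 for genes overlapped over at least 0.5 of their length. In DA_YPD the overlapped genes had a median density of 0.960 and the others 0.376, whereas in WT_YPD they had 1.21 and 1.56. XUTs with an opposite-strand partner had a median density of 1.43 in DA_YPD against 0.231 without (1177 and 228 features), and SUTs 2.04 against 0.223 (514 and 181 features). The WT_YPD medians were 0 for both sets of XUTs and 0.196 and 0 for SUTs, so no change from WT is given for them. The gene difference was present in each of 4 bins of gene length, between 1.28 and 1.88 in YPD and between 1.10 and 1.5 at SPII8h.

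**Figure D3:**
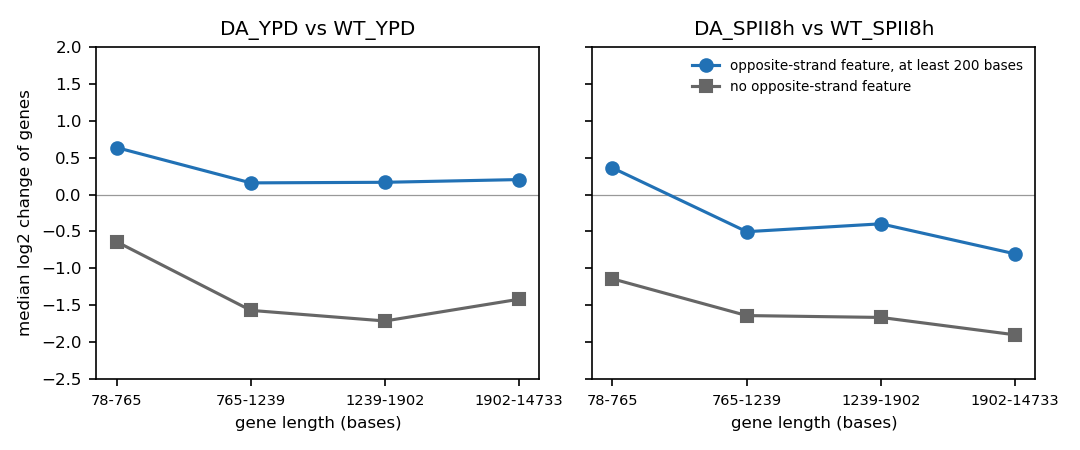
Median log2 change with DCR1 AGO1 (vertical axis) of genes in 4 bins of gene length in bases (horizontal axis), in YPD and at SPII8h, for genes with at least 200 bases of opposite-strand overlap (circles) and with none (squares). The circles lie above the squares in each bin, by 1.28 to 1.88 in YPD and 1.10 to 1.5 at SPII8h. At SPII8h the difference over all lengths was 1.24 as deposited and 1.71 with snoRNA scaling, which also moves the zero line.

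The comparison of DA_SPII8h with DA_YPD asks how the small RNA population of cells with the pathway changed in meiosis. Several genes of nitrogen uptake were among the 8 largest gene rises, together with their antisense transcripts; no list of such genes was tested. The allantoin permease gene DAL4 (YIR028W, chromosome 9, 408468 to 410375) rose from 0.156 ± 0.00339 to 26.8 ± 0.262, 172-fold (123 to 246; limma log2 change 6.73 ± 0.52, adjusted p = 0.00312), and its antisense features XUT1352 and SUT614, which share reads, rose 142-fold (104 to 200) and 111-fold (85.3 to 147). The general amino acid permease gene GAP1 (YKR039W, chromosome 11, 515063 to 516871) rose 73.6-fold (56.9 to 96.8) and its antisense SUT1912 81.5-fold (65.5 to 103). The lysine permease gene LYP1 (YNL268W, chromosome 14, 138550 to 140385) rose from 6.34 ± 0.774 to 180 ± 2.69, 28.6-fold (27.1 to 30.2), and its antisense MUT1189 from 62.6 ± 15.2 to 8286 ± 802, 132-fold (124 to 141), with 24.1% of MUT1189's 22-mers repeated. The aromatic aminotransferase gene ARO9 (YHR137W) rose 71.7-fold, the hexose transporter gene HXT10 (YFL011W) 210-fold (81.6 to 771), the largest ratio of the 8, and the iron-responsive cell wall gene FIT2 (YOR382W) 130-fold (95 to 185), with the largest log2 change, 6.84.

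The hexose transporter gene HXT3 (YDR345C, chromosome 4, 1162957 to 1164660; 29.5% of 22-mers repeated) fell from 19.8 ± 0.806 to 0.0976 ± 0.0343, 200-fold lower. The ferric reductase gene FRE6 (YLL051C, chromosome 12, 37333 to 39471) fell from 94.9 ± 0.786 to 3.26 ± 0.109, 29.1-fold lower (limma log2 change −4.82 ± 0.19, adjusted p = 0.00249), and its antisense SUT2075 fell from 85.2 ± 7.90 to 2.65 ± 0.0985. FLC1 was 22-fold lower and its antisense CUT884 15.8-fold lower, and the amino acid transporter gene TAT1 (YBR069C) was 20.6-fold lower. RPR1, the RNA of RNase P, rose 4.42-fold (3.94 to 4.96) and TLC1, the telomerase RNA, was 7.59-fold lower.

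Meiotic genes had small stage changes in DA as deposited, and more of them were called with snoRNA scaling and with limma-voom. Of 30 early meiotic genes 9 were higher and 1 lower (11 and 1 adjusted over the list alone), among them the recombination gene REC107, 3.87-fold higher (3.58 to 4.18). Their median log2 change was 0.89, and 1.64 with genes at 0 at their bound (limma camera, adjusted p = 1.86e-07, and adjusted p = 0.0843 with an estimated correlation). Of 30 middle meiotic genes 6 were higher and 3 lower (10 and 4 adjusted over the list alone), and SMK1 was among the lower ones, 5.92-fold. The middle meiotic median was 0.88, and 1.52 at the bound (adjusted p = 3.34e-05, and adjusted p = 0.190 with an estimated correlation). Of 17 spore wall genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone), with the chitin deacetylase gene CDA2 at least 25.3-fold higher. The spore wall median was 0.41, and 0.66 at the bound (adjusted p = 0.00419, and adjusted p = 0.393 with an estimated correlation). Gluconeogenesis and respiration genes had 8 higher and 4 lower of 25 (9 and 5 adjusted over the list alone). Their median was 0.45 (adjusted p = 0.00198, and adjusted p = 0.250 with an estimated correlation). The aldehyde dehydrogenase gene ALD4 rose 5.41-fold (5.0 to 5.86) and the ATP synthase gene ATP2 was 5.51-fold lower. With snoRNA scaling 18 early genes were higher and 1 lower, 20 and 2 middle, 9 and 0 spore wall and 13 and 1 gluconeogenesis and respiration genes, against 16 and 5, 17 and 5, 7 and 3, and 11 and 8 with limma-voom.

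Ribosomal protein genes had 14 lower and 0 higher of 29 between the DA stages (18 and 0 adjusted over the list alone), and RPS3 was 7.64-fold lower. The ribosomal protein median was −1.32 (adjusted p = 4.40e-05, and adjusted p = 0.126 with an estimated correlation). Glycolysis genes had 6 lower and 0 higher of 17 (11 and 0 adjusted over the list alone), and the pyruvate kinase gene CDC19 was 4.67-fold lower. The glycolysis median was −0.72 (adjusted p = 0.00373, and adjusted p = 0.167 with an estimated correlation). Mitochondrial genes had 6 of 8 lower and 0 higher (7 and 0 adjusted over the list alone). The mitochondrial median was −2.55 (adjusted p = 0.000229, and adjusted p = 0.190 with an estimated correlation). Ribosome biogenesis genes had 0 higher and 5 lower (0 and 5 adjusted over the list alone, median −0.61, and −1.32 at the bound, adjusted p = 0.763). RNA decay genes had 0 and 2 (0 and 2 adjusted over the list alone, median −0.73, and −1.23 at the bound, adjusted p = 0.335). Heat shock genes had 2 and 8 (3 and 8 adjusted over the list alone, median −0.33, adjusted p = 0.760). The published antisense list had 0 and 4 (0 and 5 adjusted over the list alone, median −0.21, adjusted p = 0.985) and the cyclin and mating list 0 and 0 (0 and 0 adjusted over the list alone, median −0.34, adjusted p = 0.838), and in both the test pointed up. With snoRNA scaling 5 ribosomal protein genes were lower and 0 higher, 4 and 1 glycolysis and 6 and 0 mitochondrial genes, against 26 and 0, 13 and 1, and 8 and 0 with limma-voom.

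Limma called 1980 features between the stages in DA, 552 higher and 1428 lower, among them 226 genes higher and 652 lower. This count was not robust to the scaling or the spread: median centring left 7 higher and 0 lower (629 at an unadjusted p under 0.05), snoRNA scaling gave 1980 and 810, quantile scaling 841 and 818, limma-voom 1327 and 5019, thinning to equal depth 184 and 419, and a spread estimated per genotype 5664 in all. Leaving out DA_SPII8h 1, DA_SPII8h 2, DA_YPD 1 or DA_YPD 2 gave 932, 989, 1059 or 1078, leaving out WT_YPD 1 or WT_YPD 2 gave 3165 or 3171, and the median change of all features moved from −0.56 to 0.22 with snoRNA scaling, 0.05 with median centring, −0.06 with quantile scaling, −0.93 with limma-voom, −0.06 at equal depth and −0.15 with a larger pseudocount.

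The comparison of WT_SPII8h with WT_YPD gives the stage difference without the pathway. Most listed meiotic genes were called higher: 27 of 30 middle, 23 of 30 early and 12 of 17 spore wall genes. In limma's camera with an estimated correlation these lists did not pass (adjusted p = 0.0712, 0.0712 and 0.116). That version uses few residual degrees of freedom and passed 0 of 48 tests, so it does not argue against these rises. The spore wall gene CDA2 (YLR308W, chromosome 12, 747937 to 748875) went from 0 to 42.1 ± 2.94, at least 51.8-fold (limma log2 change 8.77 ± 0.26, adjusted p = 0.000325), the sporulation glucoamylase gene SGA1 (YIL099W, chromosome 9, 178004 to 179653) at least 81.5-fold, SPO19 at least 34.6-fold and SPR2 (YOR214C, chromosome 15, 745593 to 746303) 334-fold against 1 WT_YPD read (59.8 to 13240). DDR2, a stress gene, rose at least 11.8-fold, and the acetate transporter gene ADY2 (YCR010C) 144-fold against 3 WT_YPD reads (49.0 to 699). Of the genes that fell, GIS4 (YML006C, chromosome 13, 256092 to 258416) went from 7.24 ± 2.53 to 0, at least 29.5-fold lower, and the alcohol dehydrogenase gene ADH5 (YBR145W) was 66.0-fold lower and the dihydroorotase gene URA4 (YLR420W) 75-fold lower, each against 1 WT_SPII8h read. Other genes with the largest fitted falls, PMP2, MRPL49, AIM1, COX17 and YER053C-A, had 4 to 10 reads in WT_YPD.

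Of 30 middle meiotic genes 27 were higher and 0 lower between the WT stages (28 and 0 adjusted over the list alone), with the phosphatase regulator gene GIP1 at least 35.1-fold and SPS2 at least 45.8-fold higher. The middle meiotic median was 6.34, and 4.62 with genes at 0 at their bound (limma camera, adjusted p = 1.48e-26, and adjusted p = 0.0712 with an estimated correlation). Of 30 early meiotic genes 23 were higher and 0 lower (25 and 0 adjusted over the list alone), with IME2 at least 24.9-fold and DMC1 at least 13.3-fold higher. The early meiotic median was 3.72, and 1.99 at the bound (adjusted p = 3.63e-18, and adjusted p = 0.0712 with an estimated correlation). Of 17 spore wall genes 12 were higher and 0 lower (15 and 0 adjusted over the list alone). The spore wall median was 3.46, and 3.41 at the bound (adjusted p = 9.79e-13, and adjusted p = 0.116 with an estimated correlation). Gluconeogenesis and respiration genes had 13 higher and 3 lower of 25 (14 and 4 adjusted over the list alone). Their median was 1.79 (adjusted p = 7.03e-05, and adjusted p = 0.190 with an estimated correlation). The acetyl-CoA synthetase gene ACS1 rose from 1.32 ± 0.552 to 160 ± 12, 104-fold (60.5 to 195), and the malate synthase gene MLS1 37.6-fold (15.9 to 117).

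Genes with a published antisense transcript had 5 higher and 2 lower of 18 between the WT stages (5 and 3 adjusted over the list alone). Their median was 0.74, and 0.46 at the bound (adjusted p = 0.0464, and adjusted p = 0.190 with an estimated correlation), and the list did not pass against protein-coding genes alone (adjusted p = 0.0543).

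Glycolysis genes had 15 of 17 lower and 0 higher (17 and 0 adjusted over the list alone), with CDC19 7.96-fold and the phosphoglycerate mutase gene GPM1 10.3-fold lower. The glycolysis median was −2.44 (adjusted p = 3.15e-12, and adjusted p = 0.0712 with an estimated correlation). Ribosomal protein genes had 18 of 29 lower and 0 higher (24 and 0 adjusted over the list alone), with RPS3 10.9-fold lower. The ribosomal protein median was −2.15 (adjusted p = 7.06e-09, and adjusted p = 0.0837 with an estimated correlation). Ribosome biogenesis genes had 5 of 29 lower and 0 higher (13 and 0 adjusted over the list alone). The biogenesis median was −1.30 (adjusted p = 0.000757, and adjusted p = 0.0837 with an estimated correlation). Mitochondrial genes had 4 of 8 lower and 0 higher (6 and 0 adjusted over the list alone). The mitochondrial median was −1.43 (adjusted p = 0.00340, and adjusted p = 0.250 with an estimated correlation). Heat shock genes had 3 higher and 7 lower of 20 (4 and 9 adjusted over the list alone, median −0.37, adjusted p = 0.0811), with HSP104 19.2-fold lower. RNA decay genes had 2 and 3 of 21 (3 and 3 adjusted over the list alone, median 0.36, and 0.20 at the bound, adjusted p = 0.886) and cyclin and mating genes 0 and 2 of 14 (0 and 2 adjusted over the list alone, median −0.65, and −0.000412 at the bound, adjusted p = 0.397). With snoRNA scaling 25 middle, 16 early and 13 spore wall genes were higher and 0 lower, while 13 glycolysis, 12 ribosomal protein and 1 biogenesis genes were lower and 0 higher.

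Limma called 1856 features between the stages in WT, 802 higher and 1054 lower, with 534 genes higher and 786 lower; tRNA genes had 10 higher and 49 lower of 204 and snoRNAs 11 and 20 of 77. The 4 WT libraries alone gave 163 calls, a spread per genotype 866, equal depth 348 higher and 442 lower, median centring 129 and 231 with a median change of −0.94 where it was 0 as deposited, limma-voom 565 and 1665 with a median of −0.83, snoRNA scaling 508 and 509 and quantile scaling 1037 and 833, and leaving out WT_YPD 1 or WT_YPD 2 gave 2959 or 3065.

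**Figure D4:**
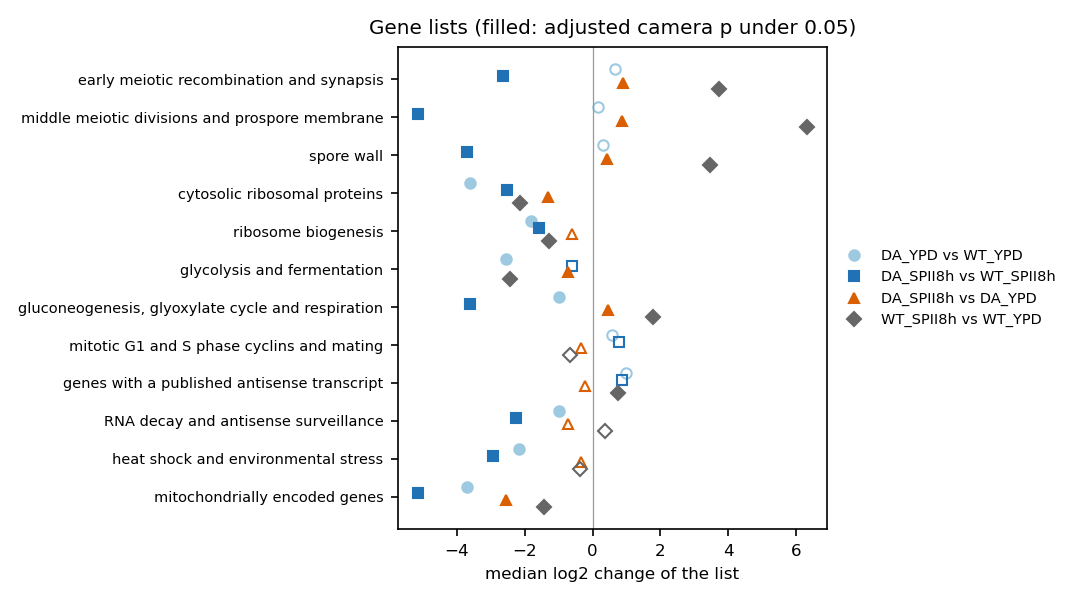
Median log2 change (horizontal axis) of 12 gene lists in the 4 contrasts; symbols mark the contrast and are filled where limma's camera passed at the preset correlation. Middle meiotic genes lay at 6.34 between the WT stages, 0.88 between the DA stages and −5.17 for DA against WT at SPII8h; with an estimated correlation no list passed (smallest adjusted p 0.0712), and scaled to the snoRNA sum the lists lower in DA against WT turned higher, such as ribosomal protein genes with 14 higher and 0 lower in YPD, or had few calls.

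The interaction tests whether the stage difference depends on the pathway. SMK1 (chromosome 16, 666280 to 667446) rose from 0 to 7.39 ± 0.165 in WT and fell from 13.5 ± 0.126 to 2.27 ± 0.216 in DA (limma log2 difference of changes −8.80 ± 0.29, adjusted p = 0.00244). NDT80, of the transcription factor that starts the middle meiotic genes, went from 0 to 13.8 ± 2.23 in WT and from 1.07 ± 0.130 to 0.377 ± 0.0653 in DA (−8.46 ± 0.40). The early gene IME2 went from 0 to 9.36 ± 1.2 in WT and stayed near 0.260 and 0.255 in DA. In the other direction XUT1592 (chromosome 13, 772791 to 773585), opposite YMR251W, had 3.56 ± 3.85 and 0 in WT and rose from 0.201 ± 0.0631 to 9.98 ± 1.07 in DA (9.75 ± 1.27, adjusted p = 0.00986). ICL1 rose from 2.39 ± 0.843 to 23.9 ± 2.16 in WT and had 81.9 ± 2.49 and 17.9 ± 0.481 in DA (−5.50 ± 0.36), and the pyruvate decarboxylase gene PDC1 had 102 ± 22.4 and 9.02 ± 1.48 in WT and 17.1 ± 0.0157 and 10.4 ± 0.194 in DA (2.76 ± 0.30).

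Of 30 middle meiotic genes 22 had a lower stage change in DA and 0 a higher one (26 and 0 adjusted over the list alone). Their median difference was −5.54 (limma camera, adjusted p = 1.13e-16, and adjusted p = 0.0823 with an estimated correlation). Of 30 early meiotic genes 15 were lower and 1 higher (21 and 2 adjusted over the list alone). The early meiotic median was −3.23 (adjusted p = 2.26e-07, and adjusted p = 0.0857 with an estimated correlation). Of 17 spore wall genes 12 were lower and 0 higher (12 and 0 adjusted over the list alone). The spore wall median was −4.16 (adjusted p = 2.24e-07, and adjusted p = 0.203 with an estimated correlation). Gluconeogenesis and respiration genes had 5 lower and 1 higher of 25 (9 and 3 adjusted over the list alone, median −0.91, adjusted p = 0.0194, and adjusted p = 0.349 with an estimated correlation). Glycolysis genes had 7 higher and 0 lower of 17 (10 and 1 adjusted over the list alone, median 1.93, adjusted p = 2.26e-07, and adjusted p = 0.0823 with an estimated correlation). With snoRNA scaling 9 middle meiotic and 3 spore wall genes were lower and 0 higher, early meiotic genes had 2 lower and 3 higher, and gluconeogenesis and respiration genes 3 and 3. With limma-voom the lower and higher genes were 20 and 0, 7 and 0, 8 and 2, and 10 and 2, and glycolysis genes had 9 higher with snoRNA scaling and 10 with limma-voom.

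Ribosomal protein genes had 1 with a higher and 3 with a lower stage change in DA of 29 (1 and 2 adjusted over the list alone). Their median was 0.61 (adjusted p = 0.0344, and adjusted p = 0.323 with an estimated correlation). Ribosome biogenesis genes had 2 and 1 of 29 (0 and 0 adjusted over the list alone). The biogenesis median was 1.14 (adjusted p = 0.0283, and adjusted p = 0.150 with an estimated correlation). Cyclin and mating genes had 1 and 0 (1 and 0 adjusted over the list alone, adjusted p = 0.240), with a median of −0.01 where the test pointed up. The published antisense list had 0 and 4 (0 and 4 adjusted over the list alone, median −1.14, adjusted p = 0.0972). RNA decay genes had 0 and 1 (0 and 0 adjusted over the list alone, median −0.82, adjusted p = 0.325). Heat shock genes had 2 and 2 (3 and 2 adjusted over the list alone, median 0.11, mean −0.04, adjusted p = 0.20), and mitochondrial genes 0 and 1 (1 and 1 adjusted over the list alone, median −1.19, adjusted p = 0.171).

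Limma called 1633 features for the interaction, 555 higher and 1078 lower. Median centring left 0 (1342 at an unadjusted p under 0.05), snoRNA scaling gave 925 higher and 287 lower, quantile scaling 684 and 833, limma-voom 771 and 1096 and a spread per genotype 879 in all, and the median of all features moved from −0.38 to 1.17, 0.30, −0.02 and −0.21 with these 4 scalings in that order. Leaving out WT_YPD 1 or WT_YPD 2 gave 2687 or 3114, with medians of −0.16 and −0.67, and a smaller and larger pseudocount moved the median to −0.69 and −0.08 and equal depth to −0.09. Leaving out DA_YPD 1, DA_SPII8h 1 or DA_SPII8h 2 gave 1087, 896 or 1002.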

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

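All 7 tests of the 3 patterns weighed here were chosen after the results were seen, and 3 of them (both for the WT reads and the pseudocount test) were rewritten, with their marks, after the values of earlier versions were known, as were the rules for reading the snoRNA test of the lower genes and the test of small RNAs present in YPD.

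The WT libraries held 840 (YPD) and 977 (SPII8h) reads at 59 noncoding features that carry at least 5000 DA reads and overlap nothing on their own strand, a median of 0.0965% of the DA reads there. As a percentage of all DA reads there, WT_YPD 1 and 2 had 0.0122 and 0.0467 and WT_SPII8h 1 and 2 had 0.0505 and 0.0179, in the order of their depths. Over these features log2 WT reads rose with log2 DA reads with a slope of 0.99 (95% interval 0.792 to 1.19), so a small carry-over of DA reads into the WT libraries is possible, although abundant transcripts of the WT cells could give such a slope too. The WT stage ratio was then fitted on the DA stage ratio. Its slope at the noncoding features minus that at 797 expressed genes was −0.286 (−0.457 to −0.115). This goes against the WT reads being fragments of transcripts that follow the same stage change. Single features went both ways. At MUT1059, which shares reads with XUT1505 and is not among the 59, WT had 11 (YPD) and 28 (SPII8h) reads where DA had 49588 and 1684. At MUT1189 WT had 20 and 44 where DA had 957 and 146167. Carry-over within a stage was the idea held first, but the stage slope at the noncoding features was −0.0402 (−0.201 to 0.121), which went against it, and carry-over from both stages, with the slope of 0.99 first set as the test against own transcripts, was taken up only then. These slopes add 0.5 reads to the WT counts of the noncoding features and the slope at genes was itself low, 0.245 (0.188 to 0.302); a binomial model of the reads with no such constant gave 0.133 (−0.134 to 0.386) and 0.703 (0.385 to 0.924), and carry-over remains a hypothesis.

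The 1980 protein-coding genes lower in DA_YPD had a median log2 change of −2.73. Scaled to the snoRNA sum 0.505% of them (10 genes) stayed lower and the median was 1.39, but that scaling lifts all DA_YPD densities alike, by 4.85 on the log2 scale, more than the median fall, so the count decides nothing. Whether a library total filled by another class of small RNAs made these falls stays open, since no measure of small RNAs per cell was used here. Thinned to equal depth the genes kept 129% of their median change, which went to −3.51. Thinning cuts mainly the DA libraries, and these genes were chosen as low there, so the fall could hardly shrink. The test therefore decides nothing about the smaller WT depth as a cause, which stays open. The 4 genes LEU1, BAT1, ILV2 and OAC1 were among the 10 that stayed lower.

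Middle meiotic genes had a smaller stage change in DA than in WT, with a median interaction of −5.54 (quartiles −6.45 and −4.71), but 17 of the 30 had 0 WT_YPD reads, 14 of the 22 called were under the pseudocount in DA_YPD, and with snoRNA scaling, which multiplies WT densities by 0.139 to 0.176 against the same pseudocount, the median was −1.64 (−3.17 and −1.03) and 8 of the 22 kept their call. Summed over the 18 listed genes under the pseudocount in DA_YPD, with nothing added, reads went from 9 to 2487 in WT and from 99 to 774 in DA, a log2 ratio of stage ratios of −4.77 (−6.47 to −3.69, and −5.23 to −4.50 without any 1 gene), so the pseudocount is unlikely to be the whole cause. The sum over all 30 was −6.44 as deposited and −5.89 (−7.70 to −4.17) scaled to snoRNAs. That scaling gives each library 1 factor and moved the sum little, so the outcome was nearly fixed by the deposited values. It says only that a shift of the size seen in the snoRNAs does not make the whole change. No measure of small RNAs per cell was used, so the library total is not excluded as a cause. The snoRNA-scaled sum leans on SMK1 and SPO20, with 1849 and 870 DA_YPD reads. Over the 18 genes, which leave both out, it was −4.14. Single genes are less settled: with WT_YPD at 3 reads where it had 0 the median of the 30 was −2.36 (−4.09 to −1.43), with both YPD counts at their one-sided 95% counting limits it was −0.44 (−2.20 to 0.52), and the pseudocount test used first, the share of the called genes whose own interval excludes no difference, gave 15 of 22 (68.2%), with 0.5 reads added. Small RNAs already present in vegetative DA cells stay open as a cause, since the share of the 22 genes higher in DA_YPD than in WT_YPD, SMK1 and NDT80 among them, was 31.8% as deposited, 59.1% with snoRNA scaling and 18.2% with limma-voom. How much of the fitted size is due to the pseudocount and the scaling stays open, and a smaller share of DA cells in meiosis was not tested.

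The interaction held 1633 features past the threshold. SMK1 had an interaction of −8.80, SUT1723 of −8.71 and XUT0217 of −8.48. CUT790 had 8.48, CUT907 9.04 and XUT1592 9.75. SUT1723 rested on 3 reads in each of WT_SPII8h and DA_YPD, and XUT0217 on 5 WT reads. The list medians of the interaction were −3.23 for early meiotic, −5.54 for middle meiotic and −4.16 for spore wall genes, 0.61 for ribosomal proteins, 1.14 for ribosome biogenesis, 1.93 for glycolysis and −0.91 for gluconeogenesis and respiration.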

How the results depend on the processing

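Read depth limits the WT side most, since features with no read there carry only a bound. Number of features past the threshold, in the order DA against WT in YPD, the same at SPII8h, stage in DA, stage in WT and interaction: median-centred libraries 3103, 2375, 7, 360 and 0, and all libraries thinned to the shallowest 2337, 2128, 603, 790 and 854. Scaled to the snoRNA sum it was 8391 at SPII8h and 1017 for the WT stage. For the DA stage it was 1271 with a mean above the median of all features, 6106 with only the 4 libraries compared, 1315 with a replicate block, 6346 with limma-voom and 5664 with a separate spread for each genotype. For the WT stage it was 163 with the 4 libraries alone and 866 with a separate spread. For the interaction it was 2520 with a 10 times larger pseudocount, 1029 with a replicate block and 879 with a separate spread. The deviations of libraries with the same replicate number were nearly uncorrelated (−0.02 to 0.0319), so no pairing by number was seen. Counting noise at features with few reads, most of all in WT, could hide a pairing.

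Leaving out 1 library gave 4476 to 6694 and 3860 to 6564 features for DA against WT in YPD and at SPII8h. It gave 932 (without DA_SPII8h replicate 1) to 3171 (without WT_YPD replicate 2) for the DA stage, 1246 to 3065 for the WT stage and 896 to 3114 for the interaction, with the lone library of a group assumed to vary like the other groups. Of 2032 named values in these fits 1881 kept their call, 144 lost it, 7 gained one and 0 turned. With an estimated correlation, where camera uses the few residual degrees of freedom, 0 gene lists passed.

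Shares without the top 1 percent of features (WT_YPD, WT_SPII8h, DA_YPD, DA_SPII8h) were 5.61, 4.64, 46.9 and 47.9% for pervasive noncoding features, 4.69, 3.82, 0.296 and 0.253% for structured RNAs and 88.5, 90.1, 51.3 and 49.8% for genes. With features above 0 in all 8 libraries pervasive shares were 1.98, 1.65 and 53.3% (first 3 groups), structured 62.2% in WT_SPII8h and 1.67% in DA_SPII8h, and genes 35.4% in WT_SPII8h and 43.5% in DA_YPD. Without genes that host structured RNAs the structured share was 65.9% in WT_YPD and 69.4% in WT_SPII8h and the gene share 30.4 and 26.9%. The difference of the median log2 densities of genes, DA minus WT, was −1.27 in YPD and −1.66 at SPII8h, and it was −0.66 in YPD and −0.73 at SPII8h with a 10 times larger pseudocount, −1.93 at SPII8h with a smaller one, and −1.64 and −1.95 with features above 0 in all 8 libraries.

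Over all features 1149 calls in YPD and 1466 at SPII8h were opposite when scaled to the snoRNA sum. Among the single features followed through all settings, those that turned sign under it were, in YPD, RPS15 (YOL040C) 1.44, NOG2 (YNR053C) 0.35, NOG1 (YPL093W) 1.47, ATP1 (YBL099W) 0.23, NDE1 (YMR145C) 0.35, PCL1 (YNL289W) 0.33, DHH1 (YDL160C) 0.68, DCP2 (YNL118C) 0.24, COX1 (Q0045) 0.27 and COX2 (Q0250) 0.60. At SPII8h they were SUT275 0.85, snR19 0.00738, SCR1 0.0283, IME2 (YJL106W) 0.55, RPP1A (YDL081C) 0.63, RPS20 (YHL015W) 1.14, NUG1 (YER006W) 0.61, FBA1 (YKL060C) 1.10, PFK2 (YMR205C) 0.79, NDE1 0.19, MUC1 (YIR019C) 2.16, DCP2 0.82, HSP42 (YDR171W) 0.20 and HSP78 (YDR258C) 0.12. Limma-voom turned tI(AAU)E1 in YPD to −2.87 and, at SPII8h, tQ(UUG)E1 to −1.97 and AGA2 (YGL032C) to −0.34. Thinning turned NAM7 (YMR080C) in the DA stage to 1.19 and NOG1 in the interaction to −1.23, and median centring turned LSR1 in YPD to −0.0832; the cause was not tested. Count models with their own size factors (edgeR, DESeq2), fixed beforehand as alternatives, were not run.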

Other observations

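The features described here were picked after their values were seen. Of the 3 tests that follow, that of the strands was rewritten after its value was known, and those of repeats and of Leu3 targets were written down before they were run but after the main results.

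The gene with the highest density in DA_YPD was HPF1 (YOL155C, chromosome 15, 28703 to 31606), which encodes a cell wall mannoprotein, with 52.0 ± 12.2 reads per kb in WT_YPD and 2836 ± 79.1 in DA_YPD (SD, n = 2). It took 7.91% of DA_YPD and 12.1% of DA_SPII8h reads, and 27.3% of its 22-mers recur in the genome. Its antisense transcript XUT0792 (28354 to 33815) had 32.0 in WT_YPD and 2704 in DA_YPD, and SUT2486 within it 65.3 and 5692. The flocculin genes FLO1 and FLO9 had 3.04 and 4.54 in WT_YPD and 226 and 271 in DA_YPD. Of their 22-mers 71.3% and 78.4% are repeated in the genome, and 41.1% and 32.3% within the gene itself. Reads may thus be shared within a gene or between family members (without repeated features and hosts of structured RNAs the YPD comparison called 5479 features). The cell wall gene DAN4 had 1.34 and 119, and PRY3, with no repeated 22-mer, 2.14 and 217.

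Genes of the 2-micron plasmid were rich in small RNAs in DA. The recombinase gene FLP1 had 13.9 ± 2.58 in WT_YPD and 1364 ± 34.0 in DA_YPD, and the partitioning genes REP1 and REP2 had 78.6 and 842, and 45.1 and 336. At SPII8h FLP1 had 18.6 and 427 and REP1 25.8 and 696. TRP1, of tryptophan synthesis, had 5.93 ± 4.19 in WT_YPD and 701 ± 3.42 in DA_YPD (limma log2 change 7.06 ± 0.54, adjusted p = 0.000346), and LEU2, of leucine synthesis, 15.1 and 49.3. HIS3, of histidine synthesis, had 1.76 and 7.99, and URA3, of uracil synthesis, 1.87 and 0.762 (adjusted p = 0.0937). LYS2, of lysine synthesis, had 7.47 and 36.9, while ADE2, of adenine synthesis, was lower, with 9.82 and 0.484 (log2 change −4.08, adjusted p = 0.000372; 0.49 with snoRNA scaling).

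The hypothesis that DA small RNAs are cut from paired transcripts of both strands predicted matched densities on the 2 strands. Over 1637 pairs of a gene and an opposite noncoding feature the Pearson correlation of log2 densities across pairs was 0.112 in WT_YPD and 0.148 in WT_SPII8h, where 56.8% and 51.9% of the noncoding members had 0 reads, against 3.05% in each DA group. To take the missing WT reads into account, the WT counts of each strand were given to the DA members in the order of their own reads and drawn again with counting noise. The DA correlations were then 0.694 and 0.722, and the lower DA value exceeded the higher WT value by 0.546, past the 0.2 set as the mark. Pairs are not independent replicates, and a shared tendency of a locus to be transcribed could also give a part of the correlation.

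The hypothesis that sequence repeated within a gene goes with more small RNAs predicted a higher DA density at such genes. The median DA_YPD density of 53 genes with at least 5% of 22-mers repeated inside the gene was 1.02, against 0.482 for 5741 others, a ratio of 2.12 (permutation test drawing random sets of genes, p = 0.00509). In WT_YPD the medians were 0.414 and 1.35. HPF1, FLO1, FLO9 and DAN4, described above after their DA densities were seen, were among the 53. Within these genes 7.98, 41.1, 32.3 and 29.8% of 22-mers are repeated. The ratio and its p thus rest in part on genes already known to be high in DA, and no value without them is given. How reads that map to several places were counted is not given in the sources used here, so mapping could likely raise or lower the density of such genes.

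The hypothesis that the falls of LEU1, BAT1, ILV2 and OAC1 extend to other targets of the activator Leu3 did not meet its prediction in YPD. As deposited ILV3, ILV5, LEU4 and GDH1 were all lower in YPD, with limma log2 changes of −4.26, −5.29, −3.57 and −1.14 (adjusted p = 0.000162, 0.000148, 0.000108 and 0.0147), as were 1980 genes. Scaled to the snoRNA sum they went both ways, from −0.64 (ILV5) to 3.65 (GDH1). Their median of 0.775 was not under −1 as predicted, and it lay past the mark set beforehand against the hypothesis. The genes are few and the scaling lifts all DA_YPD densities alike, so the result holds for that scaling only. Among 1336 genes with at least 20 WT_YPD reads the snoRNA-scaled median was 2.06, and 22.8% lay below 0.775. At SPII8h the snoRNA-scaled changes of LEU1, BAT1 and ILV2 were −0.70, −0.84 and −0.39 (adjusted p = 0.152, 0.0827 and 0.404), and OAC1 was higher, 2.10 (adjusted p = 0.00128).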
